A study of Rattus norvegicus with 6 samples.

How the data were processed

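RNA from 6 libraries of rat H9C2 cells was measured by RNA sequencing, 2 each of untreated cells (Ctrl), cells in 33 mM glucose for 8 h (HG), and cells transfected with FGFR1 siRNA before the same glucose dose (siFGFR1+HG). Per the submitters' processing notes, total RNA was extracted with TRIzol and reads were handled with fastp, HISAT2 and StringTie, with no versions given. The notes name the human genome build GRCh38, while all 32623 gene identifiers in the table are rat identifiers. The build is therefore unsure, and coordinates are given as in the table.

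The deposited table gives a count per gene and library, which per the submitters' processing notes came from those tools and which was not scaled between libraries. The deposited FPKM values were made by the authors by scaling each count to gene length and library size, and an FPKM of 0.0001 stands for a count of 0. Small counts had local peaks at 4, 8 and 12 (2362, 1331 and 724 gene and library pairs), while counts of 1, 2 and 3 were also frequent (1442, 1425 and 1142), so the number of counts per fragment is not known. The floor for genes near 0 assumed 4 counts per fragment, and a smaller number would make the floor lower and the lower bounds on folds larger. Counts per library summed to between 46960084 and 75021470. At this depth the median standard error of a log2 fold change over tested genes was 0.0870, and 13814 genes had 0 counts in all libraries.

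The gene lists, the rule for naming genes and the filter were chosen before the data were examined, from the labels alone. That plan held a limma fit on log2(FPKM + 1), because only the name of the table was known. The table turned out to hold counts, so edgeR's quasi-likelihood test was used instead, a choice made before any test was run, and the limma fit became an alternative. Genes with at least 1 FPKM in at least 2 libraries were tested (12229 genes). Counts were scaled by trimmed mean of M values (factors 0.994 to 1.01) and fitted in edgeR 4.0.16 under R 4.3.3 with 1 mean per group over all 6 libraries, which left 3 residual degrees of freedom. The common dispersion was 0.0298 and the prior degrees of freedom 3.44. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of the 3 comparisons, with no fold limit. Values after a ± sign are standard errors for log2 fold changes and standard deviations of 2 libraries for FPKM. The standard errors were worked back from the quasi-likelihood F statistic of the fit over all 6 libraries.

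In total 26 gene lists were fixed beforehand: FGF receptors, ligands and adaptors, ERK pathway targets, NF-kB and inflammatory genes, the Toll-like receptor pathway, extracellular matrix, cardiac hypertrophy genes, skeletal muscle differentiation, glycolysis, glucose-sensing and osmotic genes, oxidative stress, unfolded protein and amino acid stress, apoptosis regulators, p53 targets, cell division, DNA replication, interferon response, cholesterol synthesis, nuclear oxidative phosphorylation, the mitochondrial genome, fatty acid oxidation, ribosomal proteins, hypoxia, and macrophage, endothelial, fibroblast and epithelial markers. Lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Counts adjusted over the list alone used the p-values of its members only. List members without a matching name in the table, such as Gapdh, Mcl1, Col1a2 and Cd36, were not analysed here.

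By the naming rule the text gives, for HG against Ctrl and for siFGFR1+HG against HG, the 10 genes that rose most and the 10 that fell most among called genes with a mean of at least 5 FPKM in either group, both libraries of one group above both of the other, and a gene symbol that was not a clone name. The rule also covers the 3 members with the smallest p of each list, not all of which are printed, and Fgfr1 to Fgfr4. Names borne by more than 1 row (1556 names) were left out of the first part. The genes Dusp6, Etv5, Fosl1, Fos, Epha4, Col3a1, Col1a1, Cdc6, Atf4, Stat2, Irf9, Ifit2, Top2a, Myog, Akr1b1, Akr1b8, Cav3, Cebpb, Ifit1, Isg15, Lif, Mx2, Letm2, Nsd3, Tap1, Trim25 and the members of KEGG pathways were chosen after their values were seen.

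The pipeline was tested on simulated data with 12229 genes, of which 50 were changed at each fold. For HG against Ctrl edgeR recovered 17 of 50 genes changed 1.5-fold, 34 changed 2-fold and 42 changed 4-fold, and 11 of its 116 calls (9.48%) were false. False calls were 2.75% for siFGFR1+HG against HG and 10.5% for siFGFR1+HG against Ctrl. On the same data DESeq2 had 23.4%, 17.9% and 20.7% false calls in the 3 comparisons. Each comparison was simulated in a single draw, with dispersions from the edgeR fit and fewer changed genes than were called in the data. These shares therefore do not carry over to the calls in the data. Camera found a planted list of 30 genes and did not call an unchanged one. These genes were simulated independently, so the preset correlation was not tested, and a single unchanged list per comparison gives no rate of false calls.

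HG against Ctrl and siFGFR1+HG against HG share the HG libraries, so the covariance of fold changes was compared with 100 simulated data sets with no group difference. The number of genes called in opposite directions was not judged against these, because they held a median of only 3 and 1 called genes in the 2 comparisons. The covariance was also taken with 1 HG library in each comparison. Alternatives chosen at the same time were no filter, a filter of 5 FPKM, median-of-ratios scaling, only the 4 libraries compared, the replicate number as a block, no trend, robust fitting, fold limits of 2, each library left out in turn, and limma on FPKM with a pseudocount of 0.1, quantile normalization or rescaling to TPM. The limma fit on log2(FPKM + 1), first written as the main fit, took the place of an alternative after the table was seen. Added after seeing the data were DESeq2 1.42.0, scaling by library size only, counts divided by 4, protein-coding genes only (11267 genes), and 287 KEGG pathways of 10 to 300 genes as annotated in the deposited table. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Reads, transcript models and splicing were not analysed here.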

Results

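RNA sequencing was used to profile H9C2 cells, a myoblast line derived from embryonic rat heart. Cells kept in medium with 1 g/L glucose were left untreated (Ctrl), exposed to 33 mM glucose for 8 h (HG), or transfected with a small interfering RNA against the FGF receptor gene Fgfr1 and then exposed to the same glucose dose (siFGFR1+HG). Each of the 3 groups held 2 libraries. The counts per library summed to 54149827 and 75021470 in Ctrl, 57813848 and 52488681 in HG, and 53339452 and 46960084 in siFGFR1+HG. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels give no library a control siRNA and do not say whether Ctrl and HG were transfected. Thus siFGFR1+HG may have differed from HG by the transfection as well as by the siRNA itself. Libraries of 1 group differed by more than counting noise, with a median chi-square per gene, on counts divided by 4, of 0.735 to 0.844 against 0.455 by chance, which does not show whether they came from separate cultures.

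Fgfr1, the gene targeted by the siRNA, was near 0 in all libraries, so the knockdown could not be checked at this depth. It had counts of 0 and 4 in Ctrl, 0 and 0 in HG, and 4 and 0 in siFGFR1+HG. Every library lay under a floor of 12 counts (3 fragments at an assumed 4 counts each), or 0.160 to 0.256 CPM, which covers counting error only, and no fold is given. In the coordinates of the deposited table Fgfr1 lies on the minus strand of chromosome 16, from 71266248 to 71319449. Its neighbours Letm2 and Nsd3 had between 266 and 2909 counts in every library. Fgfr2, another FGF receptor gene, had the most counts of Fgfr1 to Fgfr4, at 7.03 to 9.54 FPKM, and was 1.31-fold higher in siFGFR1+HG than in HG (log2 0.39 ± 0.06, SE, n = 2 per group). Fgfr3 stayed at 1.26 to 2.17 FPKM and did not pass the test in that comparison (log2 0.47 ± 0.19), and Fgfr4, at 0.134 to 0.255 FPKM, was under the level at which genes were tested.

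The comparison of HG with Ctrl asks which transcripts differ after high glucose. No group in the labels is an osmotic control, so glucose itself cannot be told from added osmolarity or handling. The chemokine gene Ccl2, which attracts monocytes, was 36.1-fold higher in HG, at 42.9 ± 0.172 FPKM against 1.16 ± 0.0789 in Ctrl (SD, n = 2). Ccl7, a second monocyte chemokine, was 24.3-fold higher, and Cxcl1, a neutrophil chemokine, was 15.4-fold higher. Genes of cholesterol synthesis moved the other way: Hmgcs1, which encodes an early enzyme of the pathway, decreased from 133 ± 2.57 to 86.8 ± 2.09 FPKM (log2 -0.63 ± 0.04, SE). Of 12229 genes tested, 1670 changed, 710 of them higher and 960 lower in HG. Of these, 66 differed at least 2-fold, 45 higher and 21 lower.

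**Figure D1:**
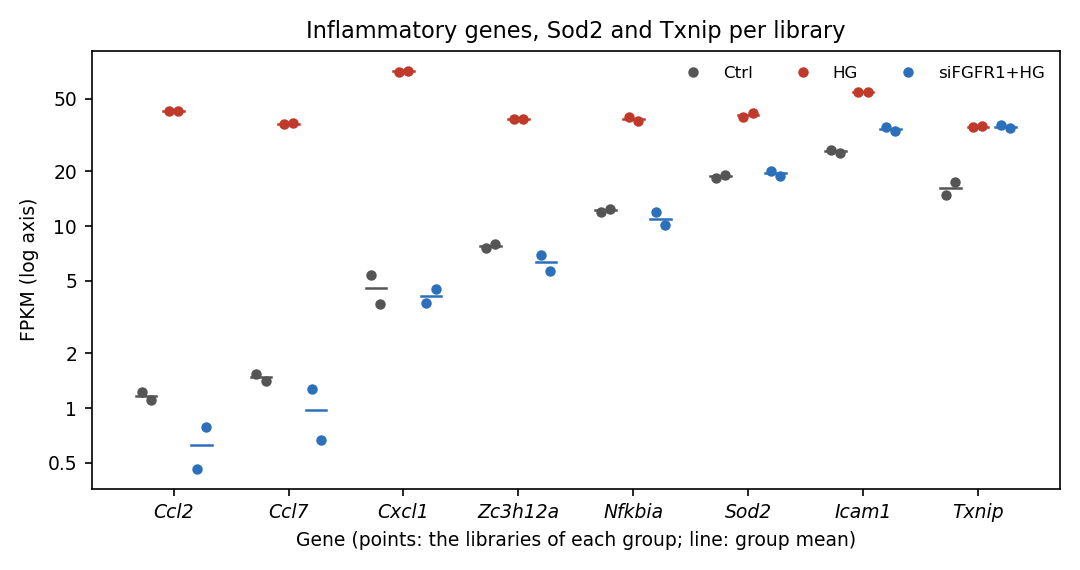
FPKM on a log axis of 8 genes in each library, with points for the 2 libraries of Ctrl, HG and siFGFR1+HG and a line for each group mean. The HG libraries lie above both other groups for Ccl2 to Icam1, while Txnip is near 35.1 FPKM in both high glucose groups and at 16.1 FPKM in Ctrl.

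Among the list of NF-kB and inflammatory genes, 17 of 23 measured members rose in HG, 0 fell and 6 were not called, against 18 higher and 0 lower when adjusted over the list alone. The list passed camera (median log2 0.48, adjusted p = 1.18e-26) and also passed with an estimated correlation (adjusted p = 0.0426). Nfkbia, which encodes an inhibitor of NF-kB, rose 3.15-fold (log2 1.66 ± 0.08), Icam1, a leukocyte adhesion molecule, 2.09-fold (1.07 ± 0.04), and Cebpd, a transcription factor of the acute-phase response, 3.76-fold (1.91 ± 0.19). Further genes with large rises were Zc3h12a (log2 2.29 ± 0.09), an RNase that degrades inflammatory mRNAs, the chemokine gene Cxcl16 (1.42 ± 0.13), the interferon-induced GTPase gene Gbp2 (1.35 ± 0.05) and Wdyhv1 (1.24 ± 0.16). The adjusted p-values of these genes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 0.000334 and 0.00725. Sod2, the mitochondrial superoxide dismutase, rose 2.15-fold (1.11 ± 0.05), within an oxidative stress list that did not pass camera (8 higher, 3 lower and 17 not called of 28 measured; 11 higher and 6 lower adjusted over the list alone). Txnip, a glucose-induced inhibitor of thioredoxin, rose 2.14-fold (1.10 ± 0.08). Rn7sl1, the RNA of the signal recognition particle, was 2.40-fold higher (1.26 ± 0.27), and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment this call was lost without any 1 of the Ctrl or HG libraries (adjusted p = 0.0680 to 0.139). The call of Wdyhv1 was lost without Ctrl 2 (adjusted p = 0.0521, same test).

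In the list of cholesterol synthesis genes, 20 of 26 measured members fell in HG, 0 rose and 6 were not called, with 21 lower and 0 higher adjusted over the list alone (median log2 -0.40, camera adjusted p = 3.06e-22). This call held with an estimated correlation (adjusted p = 0.0372). Insig1, a sterol-regulated retention factor, fell (log2 -0.68 ± 0.04), as did Cyp51, the lanosterol demethylase (-0.45 ± 0.03). The fatty acid synthesis genes Fasn (-0.59 ± 0.03) and Acaca (-0.56 ± 0.05) fell as well, in a glucose-sensing and osmotic list that did not pass camera (4 higher, 7 lower, 8 not called of 19; 4 higher and 7 lower adjusted over the list alone). Cell division genes were lower, with 16 of 32 measured members down and 0 up (20 and 0 adjusted over the list alone, median log2 -0.21, camera adjusted p = 1.03e-10). That call was lost with an estimated correlation (adjusted p = 0.130). Mki67, a proliferation marker, fell by 0.49 ± 0.03 on the log2 scale. DNA replication genes showed 9 lower and 0 higher of 34 (15 and 0 adjusted over the list alone, median -0.16, camera adjusted p = 6.35e-06; adjusted p = 0.195 with an estimated correlation), among them Uhrf1 (-0.44 ± 0.04) and Pole (-0.40 ± 0.05). The genes with the largest falls by the naming rule were Pigc (-1.35 ± 0.07), which acts in the synthesis of membrane anchors, Lpp (-1.13 ± 0.17), Prima1 (-1.08 ± 0.12), Agfg2 (-0.94 ± 0.06), Egr1, an immediate-early transcription factor (-0.87 ± 0.04), Arrdc3 (-0.85 ± 0.12), and Ep300, a histone acetyltransferase (-0.79 ± 0.13). Ano6 (-0.94 ± 0.23) and Cox6a2 (-0.79 ± 0.19) were also called. Of these, the calls of Lpp, Arrdc3, Ep300, Ano6 and Cox6a2 were lost without at least 1 of the Ctrl or HG libraries. Hiatl3 had 1123 and 1514 counts in Ctrl and 0 in both HG libraries, at least 93.8-fold lower against the floor of 12 counts per library. Its counts of 0 and 11 in siFGFR1+HG were under that floor too. The call of Hiatl3 was lost in 1 of 21 alternatives, and the floor covers counting error only. Large jumps also occurred within groups. Of the 12229 tested genes, 82 differed at least 10-fold between the 2 libraries of a group, with at least 5 FPKM in the higher library.

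Other lists that passed camera had small shifts, and each of these calls was lost with an estimated correlation. The unfolded protein and amino acid stress list had 12 higher, 1 lower and 22 not called of 35 (15 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.000272, and adjusted p = 0.130 with an estimated correlation), led by Asns, which makes asparagine (log2 0.38 ± 0.03). Cytosolic ribosomal proteins had 19 higher, 0 lower and 53 not called of 72 (25 and 0 adjusted over the list alone; median log2 0.10; camera adjusted p = 3.50e-05, and adjusted p = 0.130 with an estimated correlation). The interferon list had 3 higher, 2 lower and 20 not called of 25 (3 and 2 adjusted over the list alone; camera adjusted p = 0.0182, and adjusted p = 0.195 with an estimated correlation). Its risen members were Gbp2, Parp14 (0.31 ± 0.07) and the peptide transporter gene Tap1 (0.38), and Trim25 (-0.25) was among those that fell. The calls of Parp14, Tap1 and Trim25 were lost without any 1 of the Ctrl or HG libraries. Nuclear oxidative phosphorylation genes had 3 higher, 0 lower and 37 not called of 40 (1 and 0 adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.353 with an estimated correlation), a call that quantile normalization also ended (camera adjusted p = 0.494). Cardiac hypertrophy and fetal heart genes had 0 higher, 3 lower and 13 not called of 16 (0 and 7 adjusted over the list alone; camera adjusted p = 0.0182, and adjusted p = 0.432 with an estimated correlation), namely Ankrd1, Myocd and Mef2a, each of which lost its call without Ctrl 2. The call of the interferon list was also lost without Ctrl 1 or HG 1, and that of the cardiac list without Ctrl 1 or HG 2. The remaining lists did not pass camera. Counts of higher and lower members were 9 and 12 of 35 for extracellular matrix (11 and 14 adjusted over the list alone), 2 and 3 of 24 for ERK pathway targets (2 and 7), 1 and 4 of 19 for muscle differentiation (1 and 6), and 1 and 4 of 21 for glycolysis (2 and 4). They were 0 and 0 of 17 for the Toll-like receptor pathway (0 and 0), with smallest adjusted p = 0.102 for Tirap by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They were 4 and 1 of 27 for apoptosis regulators (4 and 1), 3 and 0 of 21 for p53 targets (3 and 2), 2 and 1 of 22 for fatty acid oxidation (3 and 2), and 1 and 2 of 19 for hypoxia genes (1 and 2). They were 0 and 2 of 13 for genes of the mitochondrial genome (0 and 2), and 1 and 2 of 14 for FGF receptors, ligands and adaptors (2 and 2).

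The count of 1670 moved with the libraries used: it was 456 without Ctrl 1, 524 without Ctrl 2, 880 without HG 1 and 729 without HG 2. On log2(FPKM + 1) values with limma, 1194 genes were called, and the split turned to 688 higher and 506 lower.

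The comparison of siFGFR1+HG with HG asks how the high glucose profile differs after the siRNA. The inflammatory genes were lower: Ccl2 was at 0.626 ± 0.231 FPKM (SD, n = 2), 66.0 times lower than in HG, Ccl7 was 36.6 times lower and Cxcl1 16.9 times lower. All 34 measured genes of DNA replication fell, among them Mcm5, a subunit of the replicative helicase, from 67.6 ± 0.0498 to 33.2 ± 0.893 FPKM (log2 -1.01 ± 0.04, SE). All 26 measured genes of cholesterol synthesis rose, among them Hmgcs1, 1.77-fold to 152 ± 2.97 FPKM. In total 3661 of 12229 genes changed, 1722 higher and 1939 lower. At least 2-fold differences were seen in 168 genes, 87 higher and 81 lower. The count of 3661 was 2380 without siFGFR1+HG 1 and 2293 without siFGFR1+HG 2, and limma on TPM turned the split to 1795 higher and 1470 lower.

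**Figure D2:**
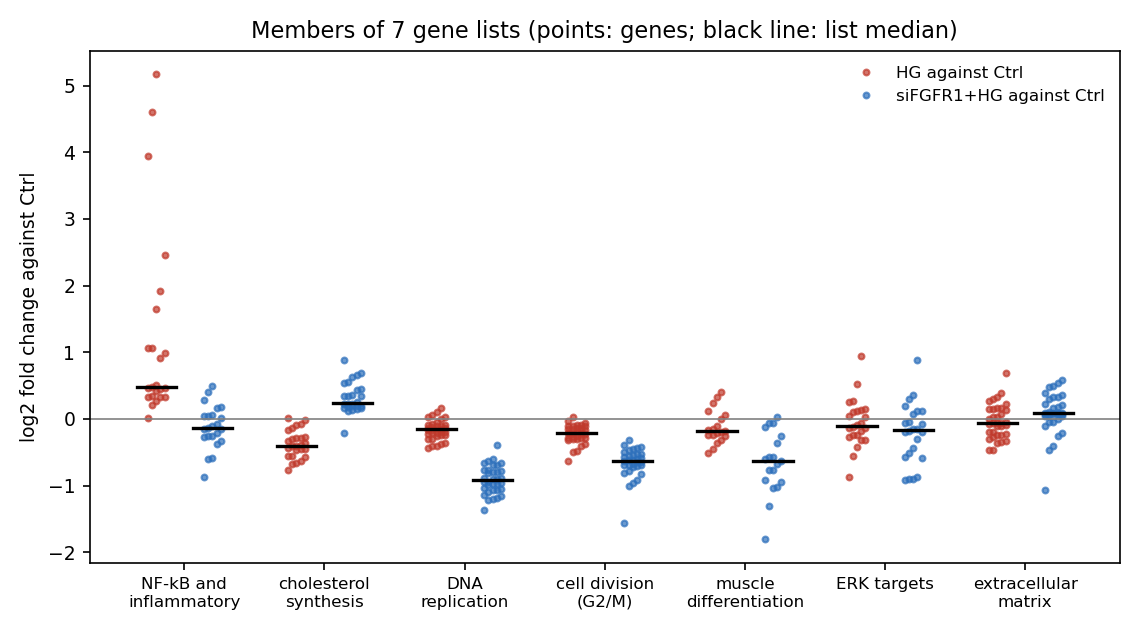
Log2 fold changes against Ctrl of the measured members of 7 gene lists, with 1 point per gene, for HG and for siFGFR1+HG, and a black line for each list median. The inflammatory list lies above 0 in HG (median 0.48) and near 0 in siFGFR1+HG (median -0.14), and the DNA replication list lies at a median of -0.16 in HG and -0.92 in siFGFR1+HG.

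In the NF-kB and inflammatory list 19 of 23 measured members fell, 0 rose and 4 were not called (22 lower and 0 higher adjusted over the list alone; median log2 -0.66; camera adjusted p = 9.16e-18). With an estimated correlation that call was lost (adjusted p = 0.0545). Besides the chemokines, Nfkbia fell by 1.81 ± 0.09 on the log2 scale, Csf1, a macrophage growth factor, by 0.82 ± 0.04, Icam1 by 0.66 ± 0.04, and Zc3h12a, outside the list, by 2.60 ± 0.09. Cxcl16 (log2 -1.55 ± 0.13), Gbp2 (-1.44 ± 0.05), Il1rl1, a receptor for interleukin-33 (-1.44 ± 0.18), Sod2 (-1.06 ± 0.05) and Tnc, a matrix glycoprotein (-1.75 ± 0.05), also fell. The adjusted p-values of these fallen genes lay between 7.31e-05 and 0.00204 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Txnip was not called (log2 0.02 ± 0.07), at 35.2 ± 0.910 FPKM against 35.1 ± 0.399 in HG.

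The DNA replication list, with 34 lower and 0 higher (34 and 0 adjusted over the list alone), had a median log2 of -0.74 (camera adjusted p = 1.38e-35; adjusted p = 0.0512 with an estimated correlation). Mcm3 (-0.94 ± 0.04) and Mcm7 (-0.87 ± 0.04), helicase subunits, and Cdc6, which loads the helicase (-1.15 ± 0.07), were examples. In the cell division list 29 of 32 fell, 0 rose and 3 were not called (29 and 0 adjusted over the list alone; median -0.41; camera adjusted p = 1.03e-18; adjusted p = 0.0628 with an estimated correlation). Examples were Ccna2, a cyclin (-0.76 ± 0.05), Foxm1, a transcription factor of mitotic genes (-0.57 ± 0.05), and Mki67 (-0.51 ± 0.03). The cholesterol list, with 26 higher and 0 lower (26 and 0 adjusted over the list alone), had a median of 0.70 (camera adjusted p = 8.81e-31) and was the 1 list whose call held with an estimated correlation in this comparison (adjusted p = 0.0227). Cyp51 rose by 0.88 ± 0.03 and Insig1 by 0.86 ± 0.04, and Scd, a fatty acid desaturase (0.94 ± 0.05), Acly (0.65 ± 0.03) and Fasn (0.56 ± 0.03) of the glucose-sensing and osmotic list rose as well. That list had 10 higher, 2 lower and 7 not called of 19 (11 and 2 adjusted over the list alone; camera adjusted p = 0.000274; adjusted p = 0.168 with an estimated correlation), and its 2 lower members were the aldose reductase genes Akr1b1 (-0.56) and Akr1b8 (-0.51).

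**Figure D3:**
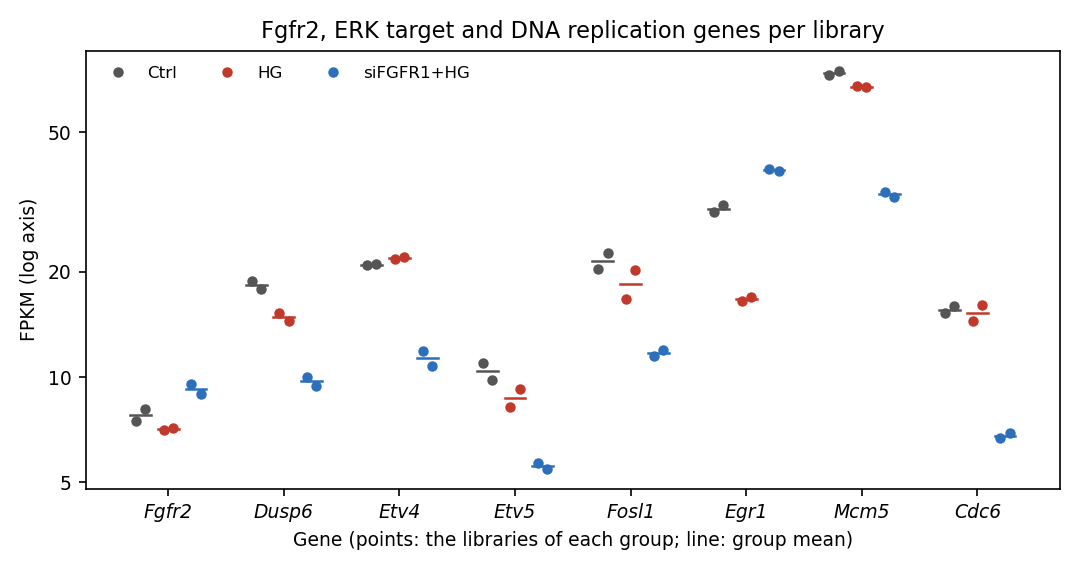
FPKM on a log axis of Fgfr2, 5 ERK pathway target genes and 2 DNA replication genes in each library, with points for the 2 libraries of each group and a line for the group mean. Etv4 is at 11.3 FPKM in siFGFR1+HG against 21.9 in HG, while Egr1 is at 39.0 against 16.7.

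Genes induced by the ERK kinase pathway, which acts downstream of FGF receptors, moved both ways: 10 of 24 fell, 3 rose and 11 were not called (10 lower and 4 higher adjusted over the list alone; median log2 -0.18; camera adjusted p = 0.0166). With an estimated correlation the call was lost (adjusted p = 0.168), as it was without siFGFR1+HG 2 (adjusted p = 0.0629). The transcription factor gene Etv4 (-0.94 ± 0.06), the cyclin gene Ccnd1 (-0.42 ± 0.03), the ERK phosphatase gene Dusp6 (-0.60 ± 0.06), Etv5 (-0.63 ± 0.09) and Fosl1 (-0.64 ± 0.10) fell, and Egr1 (1.23 ± 0.04), Fos (0.78 ± 0.22) and Epha4 (0.37 ± 0.07) rose. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Fos lost its call without any 1 of the 6 libraries (adjusted p = 0.0630 to 0.161), and Epha4 without HG 1 (adjusted p = 0.0544). Muscle differentiation genes had 2 higher, 9 lower and 8 not called of 19 (2 and 13 adjusted over the list alone; median -0.44; camera adjusted p = 5.86e-05; adjusted p = 0.168 with an estimated correlation). Embryonic myosin Myh3 (-0.83 ± 0.10), Myh4 (-0.58 ± 0.07) and the myogenic factor Myog (-0.44 ± 0.07) fell, and Cdh15 (0.13) and Cav3 (0.26) rose, though both lost their calls without either siFGFR1+HG library. Extracellular matrix genes had 18 higher, 3 lower and 14 not called of 35 (19 and 4 adjusted over the list alone; median 0.14; camera adjusted p = 0.00135; adjusted p = 0.164 with an estimated correlation). Among them Col3a1 (0.77 ± 0.05), Col5a1 (0.44 ± 0.02), Col1a1 (0.40 ± 0.03) and Fn1 (0.29 ± 0.02) rose. The fibroblast marker list, of which 6 of 15 genes were measured, had 4 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0129; adjusted p = 0.168 with an estimated correlation), led by Ddr2 (0.57 ± 0.05) and Pdgfrb (0.29 ± 0.04).

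By the naming rule the largest rises were Pigc (1.33 ± 0.07), Prrx2, a mesenchymal homeobox factor (1.29 ± 0.15), Soga1 (1.27 ± 0.12), Fgf18, an FGF ligand (1.26 ± 0.31), Egr1, Klf2, a transcription factor (1.23 ± 0.12), Synpo, an actin-binding protein (1.21 ± 0.15), Npr3, the natriuretic peptide clearance receptor (1.19 ± 0.09), Acss2, which makes acetyl-CoA from acetate (1.19 ± 0.08), and Mmp28 (1.11 ± 0.14). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Fgf18 lost its call without HG 2, siFGFR1+HG 1 or siFGFR1+HG 2 (adjusted p = 0.0622 to 0.112). Xlr3a had counts of 403 and 506 in HG and 0 in both siFGFR1+HG libraries, at least 34.6-fold lower against the same floor. Its Ctrl libraries had 0 and 305, and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its call was lost without any 1 HG or siFGFR1+HG library (adjusted p = 0.0918 to 0.143). Ribosomal protein genes had 0 higher, 20 lower and 52 not called of 72 (0 and 18 adjusted over the list alone; median -0.09; camera adjusted p = 0.00832; adjusted p = 0.179 with an estimated correlation). Quantile normalization also ended this call (median -0.03, camera adjusted p = 0.221). Oxidative phosphorylation genes had 0 higher and 5 lower of 40 (0 and 1 adjusted over the list alone; camera adjusted p = 0.0292; adjusted p = 0.268 with an estimated correlation). This call was lost in 7 of 22 alternatives, among them quantile normalization (median -0.01, camera adjusted p = 0.808), rescaling to TPM and leaving out siFGFR1+HG 2. The interferon list (4 higher, 7 lower of 25; 4 and 9 adjusted over the list alone) and the cardiac list (6 higher, 3 lower of 16; 6 and 3 adjusted over the list alone) did not pass camera, though Tnnt2, cardiac troponin T, fell by 0.72 ± 0.04. The FGF list, with 5 higher and 2 lower of 14 (5 and 3 adjusted over the list alone), did not pass either. Higher and lower members in the other lists that did not pass were 12 and 5 of 35 for unfolded protein and amino acid stress (12 and 5 adjusted over the list alone), 2 and 8 of 27 for apoptosis regulators (2 and 9), 1 and 6 of 21 for p53 targets (1 and 7), and 3 and 7 of 21 for glycolysis (5 and 7). They were 4 and 7 of 28 for oxidative stress (4 and 7), 4 and 1 of 19 for hypoxia genes (4 and 1), 2 and 3 of 22 for fatty acid oxidation (2 and 3; Angptl4, which inhibits lipoprotein lipase, fell by 2.18 ± 0.28), 2 and 0 of 13 for the mitochondrial genome (2 and 0), and 2 and 1 of 17 for the Toll-like receptor pathway (1 and 0). The 3 called members of that pathway list were Tirap and Irak3, both higher, and Traf3, lower. Irak3 kept its call in every alternative, while Tirap lost it without any 1 of the 6 libraries and Traf3 without HG 1 or either siFGFR1+HG library.

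Many genes called in HG against Ctrl were called in the opposite direction in siFGFR1+HG against HG. They numbered 973, or 58.3% of the 1670 genes changed in HG. Of these 378 had risen and then fell, such as Ccl2, Nfkbia and Sod2, and 595 had fallen and then rose, such as Pigc, Hmgcs1 and Agfg2. Another 166 were called in the same direction in both, among them Mki67, and 531 were not called in the second comparison, among them Txnip and Prima1. Both comparisons use the HG libraries with opposite sign, so chance alone favours opposite signs. Independent lists of these sizes would share 248 genes in opposite directions and 252 in the same, values that take no account of the shared libraries, so part of the excess over them may come from the sharing. Simulated unchanged groups gave a median of 0 opposite calls, but with a median of only 3 and 1 called genes in the 2 comparisons. The covariance of the fold changes across genes was -0.0511, against a median of -0.0262 and a range of -0.0345 to -0.0208 in 100 simulations of unchanged groups. It differed from that median by -0.0248. The correlation across genes, which are not independent replicates, was -0.497, the same as the simulated median of -0.497. The share of genes with opposite signs, 67.3%, lay within the simulated range of 65.7% to 67.4% (median 66.7%). With 1 HG library given to each comparison the covariance was -0.0214, against -0.00929 to 0.00806 in simulations. The count of 973 was 291 without Ctrl 1, 360 without Ctrl 2, 557 without HG 1, 469 without HG 2 and 603 without siFGFR1+HG 2.

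The comparison of siFGFR1+HG with Ctrl shows which genes still differed from untreated cells. Of the 973 genes above, 731 were not called here, 48 were still called in the direction of HG and 194 in the opposite direction. The choice of these genes, with HG apart from both other groups, itself favours small differences between siFGFR1+HG and Ctrl. No expected numbers were computed for this, and a gene not called need not be back at the Ctrl level. Ccl7 (log2 -0.59 ± 0.27) and Cxcl1 (-0.14 ± 0.18) were not called, and Icam1 remained higher than in Ctrl (0.40 ± 0.04). Txnip was 2.17-fold higher than in Ctrl (1.12 ± 0.08). Mcm5 (-1.16 ± 0.04) and Mki67 (-1.01 ± 0.03) were lower than in Ctrl. In all 2723 genes changed, 1201 higher and 1522 lower, of which 1850 also changed in the same direction against HG. Both comparisons use the siFGFR1+HG libraries with the same sign, so chance alone favours agreement, and no expected number was computed. The NF-kB and inflammatory list had 2 higher, 3 lower and 18 not called of 23 (1 and 1 adjusted over the list alone) and did not pass camera (adjusted p = 0.687). Its called members were Icam1 and Cebpb, higher, and Csf1, Lif and Ccl2, lower, and the call of Ccl2 (log2 -0.87 ± 0.24) was lost in 13 of 21 alternatives. Those of Lif and Cebpb were lost without any 1 of the 6 libraries.

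In this comparison the camera calls of 3 lists held with an estimated correlation, each at adjusted p = 0.0309. They were DNA replication (0 higher and 34 lower of 34, also adjusted over the list alone; median log2 -0.92), cell division (0 and 29 of 32; 0 and 30 adjusted over the list alone; median -0.62) and cholesterol synthesis (21 and 0 of 26; 25 and 0 adjusted over the list alone; median 0.24). Among their members Cdc6 (-1.20 ± 0.07), Top2a, a DNA topoisomerase (-0.91 ± 0.05), and Cyp51 (0.44) differed from Ctrl. Muscle differentiation had 0 higher and 12 lower of 19 (0 and 14 adjusted over the list alone; median -0.63; camera adjusted p = 3.58e-08; adjusted p = 0.127 with an estimated correlation). The unfolded protein and amino acid stress list had 14 higher and 2 lower of 35 (14 and 3 adjusted over the list alone; camera adjusted p = 1.57e-05; adjusted p = 0.0752 with an estimated correlation). Its members included Asns (0.64 ± 0.03), Atf4, a stress-induced transcription factor (0.49 ± 0.03), and Chac1 (0.65 ± 0.05), which degrades glutathione. ERK pathway targets had 3 higher and 8 lower of 24 (3 and 11 adjusted over the list alone; camera adjusted p = 0.00867; adjusted p = 0.173 with an estimated correlation), with Dusp6 at -0.92 ± 0.06, Etv4 at -0.90 ± 0.06 and Ccnd1 at -0.51 ± 0.03. Extracellular matrix genes (13 higher and 4 lower of 35; 16 and 7 adjusted over the list alone; camera adjusted p = 0.0101; adjusted p = 0.173 with an estimated correlation) also passed. So did the glucose-sensing and osmotic list (8 and 2 of 19; 9 and 2 adjusted over the list alone; camera adjusted p = 0.00202; adjusted p = 0.231 with an estimated correlation). Glycolysis genes (1 and 8 of 21; 1 and 9 adjusted over the list alone; camera adjusted p = 0.0201; adjusted p = 0.422 with an estimated correlation) passed with all libraries and missed the threshold without Ctrl 2 (adjusted p = 0.0571). The interferon list did not pass (4 higher and 2 lower of 25; 4 and 2 adjusted over the list alone; camera adjusted p = 0.837). Its risen members included Stat2 and Irf9, transcription factors of the response, and the induced gene Ifit2, while the induced genes Isg15, Ifit1 and Mx2 were not called. The calls of Irf9 and Ifit2 were lost without any 1 of the Ctrl or siFGFR1+HG libraries. Higher and lower members in the other lists that did not pass were 3 and 0 of 14 for FGF receptors, ligands and adaptors (3 and 0 adjusted over the list alone), 1 and 0 of 17 for the Toll-like receptor pathway (1 and 0), 3 and 2 of 16 for cardiac genes (3 and 3), and 7 and 3 of 28 for oxidative stress (9 and 4). They were 2 and 6 of 27 for apoptosis regulators (2 and 6), 1 and 3 of 21 for p53 targets (0 and 1), 2 and 3 of 40 for oxidative phosphorylation (0 and 0), 0 and 1 of 13 for the mitochondrial genome (0 and 0), 2 and 4 of 22 for fatty acid oxidation (2 and 4), 4 and 6 of 72 for ribosomal proteins (2 and 1), and 5 and 0 of 19 for hypoxia genes (5 and 2). The count of 2723 fell to 1490 without Ctrl 1, 1379 without Ctrl 2, 1470 without siFGFR1+HG 1 and 1553 without siFGFR1+HG 2.

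Leukocyte, epithelial and endothelial markers were scarce, while 6 of 15 fibroblast markers reached the level tested. Of the 17 macrophage and leukocyte markers 2 reached the level tested, Cd68 (0.423 to 1.31 FPKM) and Fcer1g, and neither was called in HG against Ctrl or in siFGFR1+HG against HG. Of 14 epithelial markers 1 was tested, Krt8, which was lower in HG than in Ctrl (log2 -0.36 ± 0.06). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment that call of Krt8 was lost without Ctrl 1, Ctrl 2 or HG 2 (adjusted p = 0.0711 to 0.0942). Of the endothelial markers 3 were tested, with 1 higher and 0 lower in HG (1 and 0 adjusted over the list alone), namely Eng (0.35 ± 0.06), and 0 called in siFGFR1+HG against HG (0 adjusted over the list alone). The call of Eng was lost without Ctrl 1 (adjusted p = 0.0698) or HG 1 (adjusted p = 0.0559) in the same test. Fibroblast markers had 0 higher and 2 lower of 6 in HG (1 and 2 adjusted over the list alone), and 2 higher and 0 lower in siFGFR1+HG against Ctrl (3 and 0 adjusted over the list alone).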

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

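No gene called in a comparison was called in the opposite direction under any alternative. HG against Ctrl had 1670 called genes. Quantile normalization in limma called 980 genes, 906 of them among the 1670, and DESeq2, added after seeing the data, called 2628, 1659 of them among the 1670. The cause of these shifts was not tested. DESeq2 also made more false calls on simulated data, but those held dispersions from the edgeR fit and fewer changed genes. A 2-fold limit left 66 genes, or 124 at unadjusted p, in HG against Ctrl, 168 or 224 in siFGFR1+HG against HG, and 145 or 198 in siFGFR1+HG against Ctrl. Leaving out 1 library left a lone sample in a group, assumed to vary like the other groups, and gave 456 to 1302, 2293 to 3247 and 1379 to 2586 genes. These fits had fewer samples. The 973 genes called in opposite directions became 530 under quantile normalization, with cause not tested, and 291 to 665 with a library left out.

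The limma fit on log2(FPKM + 1), first written as the main fit and made an alternative after the table was seen, gave 1194 genes in HG against Ctrl, 688 higher and 506 lower against 710 and 960, and 1100 were shared. Limma on TPM gave 406 higher and 749 lower, limma with quantile normalization 401 and 579, and edgeR scaled by library size only 872 and 869. In siFGFR1+HG against HG 1722 were higher and 1939 lower, against 1795 and 1470 for limma on TPM, 1600 and 1488 for limma with quantile normalization, and 1604 and 1572 with only the 4 libraries compared. Which direction held more genes thus varied between alternatives in both comparisons, and the cause was not tested. The covariance of fold changes of -0.0511 became -0.0214 with the HG libraries split, which removes the shared samples, and -0.112 with a pseudocount of 0.1, which widens the folds of low genes and the simulated values with no group difference too (median -0.0531, range -0.0666 to -0.0430).

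Gene lists past camera numbered 9, 11 and 9 in the 3 comparisons, against 2, 1 and 3 with an estimated correlation and 15, 19 and 14 with fry, which tests each list without regard to other genes. Of 29 list calls 6 held in every alternative. With the replicate block 1153, 3253 and 2323 genes were called. The numbers may be shared in name only, as deviations of libraries with the same number correlated at 0.0595, 0.0514 and -0.0896 between groups.

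Of 165 values of genes named by the rule that passed the threshold, 116 passed in every alternative. Without Ctrl 1 35 were lost, and with counts divided by 4 0 were lost. Fgfr1, with 0 to 4 counts in all libraries, cannot be compared at this depth, so no alternative was run for it.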

Other observations

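The tests of KEGG pathways were chosen only after the results were seen, and of the 287 pathways 0 passed camera with an estimated correlation in any comparison. Proteasome genes, which encode the protease that degrades marked proteins, had 12 higher, 0 lower and 32 not called of 44 in HG against Ctrl (18 and 0 adjusted over the list alone; median log2 0.16; camera adjusted p = 1.49e-08; adjusted p = 0.418 with an estimated correlation). Psme2 (0.85 ± 0.07) and Psmb10 (0.90 ± 0.10), parts of the interferon-inducible proteasome, and Psmd8 (0.36 ± 0.03) rose. In siFGFR1+HG against HG 1 proteasome gene was higher and 30 lower of 44 (1 and 37 adjusted over the list alone; median -0.20; camera adjusted p = 2.24e-08; adjusted p = 0.287 with an estimated correlation), with Psme2 at -0.82 ± 0.07 and Psme1 at -0.50 ± 0.05. Under quantile normalization the proteasome medians were 0.11 and -0.12 in these 2 comparisons. Spliceosome genes had 1 higher and 76 lower of 130 in siFGFR1+HG against HG (1 and 81 adjusted over the list alone; median -0.23; camera adjusted p = 7.13e-12; adjusted p = 0.278 with an estimated correlation), among them the splicing factors Srsf2 (-0.46 ± 0.03) and Srsf7 (-0.45 ± 0.03), with a median of -0.18 under quantile normalization. Lysosome genes had 35 higher and 2 lower of 94 in siFGFR1+HG against Ctrl (41 and 5 adjusted over the list alone; median 0.14; camera adjusted p = 1.57e-05; adjusted p = 0.318 with an estimated correlation), such as the proteases Ctsa (0.33 ± 0.03) and Ctsd (0.26 ± 0.02) and the lipase Lipa (0.34 ± 0.03), with a median of 0.17 under quantile normalization.

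Rn7sl1, the RNA of the signal recognition particle, was 2.09-fold higher in siFGFR1+HG than in HG (log2 1.06 ± 0.27) and 5.02-fold higher than in Ctrl (2.33 ± 0.28). The first of these Rn7sl1 calls was lost without HG 1, HG 2 or siFGFR1+HG 1. Other structural RNAs were chosen after their values were seen. In siFGFR1+HG against HG 2 of 10 copies of 7SK (median log2 1.48) and 1 of 2 further signal recognition particle RNAs (median 1.18) were higher, and the RNA of RNase MRP (1.26) was not called, though it was higher than in Ctrl (2.09). The small nuclear RNA families U1, U2 and U6 had 0 called of 13, 10 and 12 tested in siFGFR1+HG against HG, and Rpph1 was not called there. Against Ctrl 1 of the U1 copies was higher.

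For the genes called in opposite directions, the test of the shared libraries was written before the result was seen and that of handling after. Shared HG libraries would give a split covariance within the simulated range of -0.00929 to 0.00806 if the HG libraries deviated independently. It was -0.0214, outside that range, so independent deviations of the kind simulated did not account for all of it. A deviation common to both HG libraries would remain after the split. Separate cultures are not stated in the labels, so the test could not settle how much came from the shared libraries. A handling difference of the HG libraries could also return genes to the Ctrl level, and the shift of siFGFR1+HG from Ctrl was a median of 0.247 times that of HG over the genes changed in HG. Those genes were chosen by the HG shift, and both shifts use the Ctrl libraries, so the ratio depends on the choice and the sharing. No expected value was computed for it. The HG libraries also stood apart in the sum of FPKM, at 542621.4 and 547167.5 against 526117.9 to 526900.5 in the Ctrl and siFGFR1+HG libraries. FPKM divides counts by gene length and library size, so a higher sum means that relatively more counts fell in shorter genes. The cause of that was not tested, nor was whether gene length bore on the genes and lists called in comparisons with HG. The data cannot separate a handling difference from an effect of the siRNA on the high glucose response. HG is the only high glucose group without FGFR1 siRNA in its label.

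For the near absence of Fgfr1, the test of missed reads was written before the result was seen and that of overlapping genes after. Reads of expressed genes missed by the counting could leave Fgfr1 at 0. Of 112 ribosomal and oxidative phosphorylation genes with a row in the table, 0 had under 10 counts in every library. Listed genes without a matching row (Rpl22, Rps14, Rps19, Rps26 and Cox7a2) were left out, and a shared name was taken at its highest row. The check could therefore not see genes that were absent from the table. Under the rule written beforehand, 0 genes under that count spoke against missed reads. Other genes cannot exclude that the reads of a single gene were missed, so, apart from that rule, this was left open. No row of the table overlapping Fgfr1 held a count, a result that would also arise if no row overlapped it. Reads of the locus were thus not counted under an overlapping row. Reads assigned to no row of the table could not be seen, so their loss was left open. No biological explanation was tested, because no other measure of the receptor was used here.

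For the lower DNA replication genes in siFGFR1+HG, the interferon test was written before the result was seen and the ERK and transfection tests after. Ranges in brackets below are 95% intervals of a list median over its members. They treat the members as independent and hold no error between libraries, so they do not measure the spread of the treatment effect. An interferon response to the siRNA would raise the interferon list over Ctrl. Its median log2 was -0.0399 (-0.23 to 0.06), with Stat2, Irf9 and Ifit2 among the higher genes and the calls of the last 2 lost without any 1 Ctrl or siFGFR1+HG library. The rule written beforehand counted a median that did not rise over Ctrl against this explanation. That rule took no account of the interval, which spans both directions, or of the higher genes, so the explanation was left open. Lower FGF receptor signalling through ERK would lower ERK targets, and their median against HG was -0.18 (-0.39 to -0.07), with camera adjusted p = 0.0166 but adjusted p = 0.168 with an estimated correlation. Transfection or off-target effects would appear against Ctrl too, where the replication median was -0.92 (-1.03 to -0.79), and without a control siRNA in the labels they could not be told from an effect of the target.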
